A study of Rattus norvegicus with 18 samples.

How the data were processed

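Total RNA from whole brains of 3 inbred rat strains was measured on 18 Agilent arrays with a single dye (Cy3). Per the labels, the strains were the normotensive Wistar-Kyoto rat (WKY), the spontaneously hypertensive rat (SHR) and the stroke-prone SHR (SHRSP). Each was sampled at 3 and at 6 weeks of age with 3 biological replicates, which made 6 groups. The sex of the animals was not given in the sources used here. Per the labels, brains were stored in a preservative and the RNA was amplified and labelled from an oligo-dT primer.

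The deposited scanner files hold 1 intensity per spot. Per the file headers, the authors used Agilent Feature Extraction 10.5.1.1, which subtracted the local background, removed spatial trends within each array and replaced values too low to use with surrogate values. Per the file headers, no step scaled the arrays to each other. The deposited table of the whole series holds the same intensity values on every array, so only the scanner files were used. Per the file headers, probe coordinates refer to the rn4 build of the rat genome. Gene symbols came from the files and were updated from a RefSeq table by accession for 17320 probes, through another probe of the same name for 199 and through a synonym for 691. Whether a probe lies in an exon or an untranslated region was not analysed here.

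The intensity of each spot was taken as log2 and the array's 75th percentile was subtracted. Control spots and spots that the files mark as population outliers or non-uniform were left out, at most 1.49% of the spots of an array. Replicate spots of a probe were averaged. Probes were kept if they were well above background, as the files mark it, on all 3 arrays of at least 1 group, which left 24284 of 30367 probes. A gene was represented by its brightest kept probe, chosen over all arrays, and 3 genes without at least 2 values in every group were left out. This gave 21197 genes, of which 14451 had a gene symbol that could be named. The rest were predicted loci, accessions and probes without a gene name. The median intensity of an array lay between 350 and 434, the share of spots well above background between 81.8% and 87.5%, and the spread of replicate spots between 3.47% and 4.94% (median coefficient of variation). No spot was saturated. Log2 values of replicate arrays correlated across genes with r between 0.9932 and 0.9975; genes are not independent replicates. The number of arrays, 3 per group, limits the precision.

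One limma fit (limma 3.58.1, R 4.3.3) with a mean for each of the 6 groups gave all 11 comparisons, with 12 residual degrees of freedom and variances moderated with 1.95 prior degrees of freedom. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05 over the 21197 genes of a comparison. Tests were two-sided. Errors are standard errors (SE) of the moderated fit. Comparisons were SHR with WKY, SHRSP with WKY and SHRSP with SHR at each age, 6 with 3 weeks in each strain, and the difference of the age change of SHR or SHRSP from that of WKY (the interaction of strain and age). Where a probe was not well above background on any array of 1 group, the change is given as "at least" a fold. That bound divides the mean of the brighter group by a mean in which each dimmer array took its own signal or the lowest signal marked well above background on it, whichever was higher.

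Gene lists of cell types, pathways and adjoining tissue (34 lists) were fixed in advance, and 33 had the 3 measured members needed. Each was tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. Of 80 shifts called so, 5 held with an estimated correlation, and each list is given with both values. Genes of a list were also counted as called when adjusted over the list alone.

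The comparisons, tests, lists, alternatives and the rule for named genes were set before the data were examined. Names were given only to genes with an established symbol. In each comparison the rule took the 8 raised and the 8 lowered called genes with the largest change that were well above background on all 6 arrays and whose groups did not overlap. It also took up to 3 genes each way that were under background in a whole group, ranked by the bound. From each list it took up to 4 called members with the smallest adjusted p, or the 2 brightest where none was called, and from the candidate hypertension list every measured member. It took the 10 largest each way among genes called in 1 direction in all 4 comparisons with WKY. It took up to 6 each way with the smallest adjusted p in each interaction. It took the 8 largest each way among genes called in 1 direction between SHRSP and SHR at both ages. Not every gene that the rule took is named in the text.

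Per the file headers, the arrays were on 5 slides scanned on 3 days. Slide 1 held the WKY arrays of 3 weeks and SHR replicate 1 of 3 weeks. Slide 2 held SHR replicates 2 and 3 and SHRSP replicates 1 and 2 of 3 weeks. Slide 3 held SHRSP replicate 3 of 3 weeks and the WKY arrays of 6 weeks. Slides 4 and 5 held the 6-week SHR and SHRSP arrays. Slides 1 and 2 were scanned on the first day, slides 3 and 4 on the second and slide 5 on the third. Slide was fitted as a fixed block (statmod 1.5.0 for the random form) for the comparisons within 3 weeks and for age in WKY, where slides connect the groups. For the rest slide was a random block with a shared correlation of 0.273, because at 6 weeks the slides of SHR and SHRSP cannot be told apart from their strains.

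The alternatives were normexp background correction with an offset of 50, quantile normalization, no filter, a filter on all 18 arrays, both slide blocks, a block on the replicate numbers of the labels, variances with a trend and robust estimates, a fit of the compared groups alone, the mean of a gene's probes, a bound of 2-fold, leaving out each array, and for lists an estimated correlation and fry. A block on scan day and a test of nameable genes alone were added after the values were seen. The pipeline was tested on simulated data for the comparison of SHR with WKY at 3 weeks, built from the mean and the moderated spread of each of 21117 genes, with 200 genes changed. Of genes changed by log2 0.5, 1 and 2, 59 of 67 (88.1%), 59 of 67 (88.1%) and 66 of 66 (100%) were recovered. There 4 unchanged genes were called, and 0 genes in the comparison of SHRSP with SHR at 6 weeks, in which none was changed. A list shifted by log2 0.5 passed and 0 other lists did. No slide effect was simulated, so false calls due to slides were not tested.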

Results

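Changes are log2 differences between group means with their SE (n = 3 arrays per group), so a difference of 1 is 2-fold. The WKY arrays are the reference background in every strain comparison. Among the largest strain differences, a set of genes followed opposite SHR and SHRSP labels at the 2 ages, so these groups are called the arrays labelled SHR and the arrays labelled SHRSP throughout. Slides and groups overlapped only in part, and values with slide as a block stand beside the results they affect.

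The 4 comparisons with WKY ask which genes set the hypertensive strains apart from it at both ages. Ptgr1, which reduces prostaglandins and leukotrienes, differed from WKY by log2 -3.90 ± 0.06 (SE, n = 3) and -4.19 ± 0.06 in the arrays labelled SHR at 3 and 6 weeks, and by -3.87 ± 0.06 in the arrays labelled SHRSP at each age. Alb, the serum albumin gene, differed by -3.66 ± 0.13 and -3.16 ± 0.13 in the arrays labelled SHR and by -3.31 ± 0.13 and -3.64 ± 0.13 in those labelled SHRSP. Acsm5, a mitochondrial medium-chain acyl-CoA synthetase, was higher by 3.18 ± 0.06, 3.75 ± 0.06, 3.05 ± 0.06 and 3.81 ± 0.06 in the same order. Adtrp, which regulates the tissue factor pathway inhibitor, was higher by 3.04 ± 0.06, 3.71 ± 0.06, 3.08 ± 0.06 and 3.56 ± 0.06. All 16 of these changes had an adjusted p of at most 3.97e-10. In the rn4 build the probes lie on chromosomes 5 (Ptgr1, 77010948 to 77011007) and 14 (Alb, 19126980 to 19127039). Those of Acsm5 and Adtrp lie on chromosomes 1 (177808482 to 177808541) and 17 (28879511 to 28879570).

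In all 4 comparisons with WKY, 541 genes rose and 422 fell, and 362 more were called in all 4 with mixed directions. An average change of at least 2-fold was reached by 64 of the raised and 76 of the lowered genes. Of the 10 with the largest average rise, Chi3l1, a secreted chitinase-like protein, was higher by log2 1.81 to 2.07 (SE 0.06). Mcm7, part of the replicative helicase, was higher by 1.93 to 2.10 (SE 0.06) and Ly75, an endocytic receptor of dendritic cells, by 2.27 to 2.82 (SE 0.10). Ly75 was well above background on 2 of 3 WKY arrays at each age. Acox2, a peroxisomal oxidase of branched fatty acids and bile acid intermediates, was under background in WKY at 3 weeks and at least 4.37-fold and at least 4.83-fold higher in the arrays labelled SHR and SHRSP. At 6 weeks, with 2 of 3 WKY arrays above background, it was higher by 2.44 ± 0.22 and 2.53 ± 0.22. Oxnad1 was under background in every WKY array and was at least 3.67-fold to at least 16.0-fold higher, a size that went with the slide, since SHR arrays on slides 1 and 4 lay between -3.79 and -3.58 and all other SHR and SHRSP arrays between -5.94 and -5.33. Of the 10 with the largest average fall, Cyp2c11, a steroid hydroxylase, dropped by 1.12 to 3.07 (SE 0.13) and Amy1, an amylase above background on 1 or 2 of the 3 arrays of each hypertensive group, dropped by 2.08 to 2.41 (SE 0.21). Ncaph, a condensin subunit, dropped by 1.74 to 2.13 (SE 0.07). St6galnac2, a sialyltransferase, was under background in every SHR and SHRSP array and at least 2.45-fold to at least 2.95-fold lower.

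**Figure D1:**
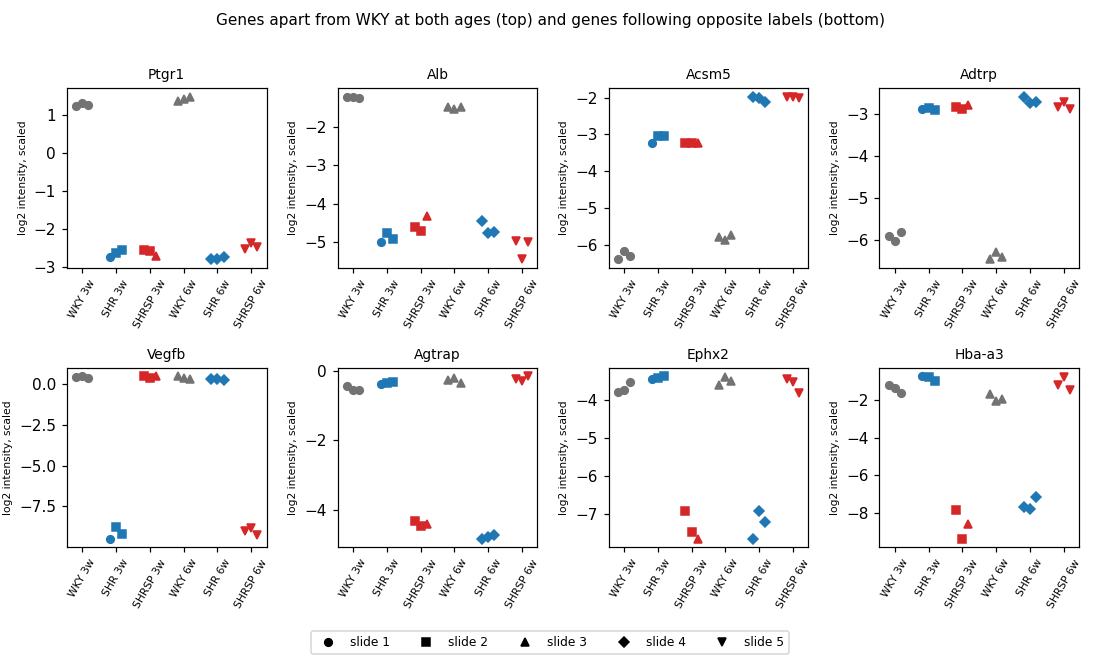
Scaled log2 intensity of 8 genes on each of the 18 arrays, with 1 point per array, the 6 groups on the horizontal axis, colour for strain label and shape for slide. Ptgr1, Alb, Acsm5 and Adtrp separated WKY from all other arrays. Vegfb was low on arrays labelled SHR at 3 and SHRSP at 6 weeks. Agtrap, Ephx2 and Hba-a3 were low on those labelled SHRSP at 3 and SHR at 6 weeks.

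SHR and SHRSP share the WKY arrays of an age, which alone correlates their differences from WKY. At 3 weeks 1889 genes rose and 3151 fell in both, against 413 and 851 for independent calls, and r across genes was 0.83, against 0.49 in simulated unchanged groups with shared WKY arrays. At 6 weeks 1784 rose and 1129 fell in both, against 1094 and 370, with r = 0.47 against 0.49. Shared arrays give such an r whatever the size of the noise, so r alone does not measure what the strains share. The covariance across genes was 0.129 at 3 weeks and 0.0695 at 6 weeks, against 0.011 in the simulated groups. Without shared arrays, r was 0.38 between the arrays labelled SHR at 3 weeks and SHRSP at 6 weeks. There 1308 genes rose and 753 fell in both against 485 and 413. Between the arrays labelled SHRSP at 3 weeks and SHR at 6 weeks r was -0.26, and within a label across ages it was -0.23 for SHR and 0.24 for SHRSP. Genes are not independent replicates, r and covariance were not adjusted for slide, and 6 such correlations were computed.

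The comparison of SHR with WKY at 3 weeks asks how the brains differ at weaning. The arrays labelled SHR had lower values of Sst, the somatostatin gene, by log2 0.74 ± 0.07 (SE, n = 3; adjusted p = 3.09e-06) and higher Sgk1, a kinase induced by corticosteroids, by 2.01 ± 0.18 (adjusted p = 2.64e-06). B3galt1, a galactosyltransferase, was higher by 1.87 ± 0.09. The slide block here compares SHR replicate 1 alone with the WKY arrays of slide 1. Its values were -0.63 for Sst, 1.87 for Sgk1, 1.81 for B3galt1, -3.99 for Ptgr1, -3.77 for Alb, 3.06 for Acsm5 and 3.03 for Adtrp. Vegfb, a vascular endothelial growth factor, was under background in all 3 arrays labelled SHR and at least 285-fold lower (adjusted p = 3.5e-15). Lilrb3l, an immunoglobulin-like receptor of leukocytes, was under background in WKY and at least 11.8-fold higher, and Ostn, osteocrin, was at least 5.53-fold lower. The angiotensin receptor gene Agtr1b fell by 2.05 ± 0.43 and the odorant receptor gene Or8b8 by 2.16 ± 0.44, but neither was called with slide as a block (adjusted p = 0.18 and 0.137).

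Meningeal and fibroblast genes were the only list that shifted between the arrays labelled SHR and WKY at 3 weeks. Of 19 measured meningeal and fibroblast genes, 8 rose and 0 fell, and the same numbers passed adjusted over the list alone (median log2 0.21; camera adjusted p = 3.37e-05, and adjusted p = 0.96 with an estimated correlation). Ptgds, the prostaglandin D synthase of the leptomeninges, rose by 0.52 ± 0.05, the GABA transporter gene Slc6a13 by 0.51 ± 0.07, Col3a1 by 0.41 ± 0.06 and Igf2 by 0.24 ± 0.05. With slide as a block, again SHR replicate 1 alone, the mean of the list was 0.26. Igf2 was not called with the block. Of the candidate hypertension genes, 6 of 21 rose and 2 fell, with 6 and 4 adjusted over the list alone. The fatty acid transporter gene Cd36 rose by 0.53 ± 0.12, the adrenal 11-beta-hydroxylase gene Cyp11b1 by 0.46 ± 0.07, Gstm1 by 0.23 ± 0.04, the angiotensinogen gene Agt by 0.19 ± 0.06 and Spon1 by 0.18 ± 0.06, while the chromogranin gene Chga fell by 0.46 ± 0.11. Of these 6 genes only Cyp11b1 was called with slide as a block (adjusted p = 0.0207), and the others were not (adjusted p between 0.0554 and 0.55). As a list they did not pass (adjusted p = 0.315).

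In total 6046 of 21197 genes were called between the arrays labelled SHR and WKY at 3 weeks, 2397 raised and 3649 lowered (39.6% raised, 55.7% after quantile normalization). The count was 1478 with slide as a fixed block, 3246 with a random slide block and 1735 in a fit of these groups alone. Of the 30 called genes that the naming rule took outside the lists, 30 had the same direction with slide as a block. The block here rests on SHR replicate 1 alone. Without WKY replicate 2 or SHR replicate 2 or 3 the count was 3871, 3327 or 3140.

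The comparison of SHRSP with WKY at 3 weeks asks the same. In the arrays labelled SHRSP, Agtrap, which binds the angiotensin II type 1 receptor, was lower by log2 3.90 ± 0.05 (SE, n = 3; adjusted p = 3.73e-15). Ephx2, the soluble epoxide hydrolase that breaks down vasodilating epoxides of arachidonic acid, was lower by 3.65 ± 0.19 (adjusted p = 5.79e-09) and above background on 2 of these 3 arrays, and Nppa, the atrial natriuretic peptide gene, by 1.07 ± 0.08 (adjusted p = 3.84e-07). The zinc finger genes Zfp597 and Zfp296 rose by 2.87 ± 0.07 and 2.24 ± 0.08, and Rgs11, a regulator of G protein signalling, by 2.40 ± 0.15. Hba-a3, an alpha globin gene, was under background in all 3 arrays and at least 80.9-fold lower, and Defb17, a defensin gene, was under background in WKY and at least 40.2-fold higher. In the rn4 build the probes lie on chromosomes 5 (Agtrap, 165154364 to 165154423), 15 (Ephx2, 45535737 to 45538220) and 10 (Hba-a3, 15559461 to 15559520). The values with slide as a block were -3.92 for Agtrap, -3.57 for Ephx2, -1.40 for Nppa and 2.76 for Zfp597, all called. Agtr1b fell by 2.85 ± 0.43 and Or8b8 by 2.96 ± 0.44, and neither was called with slide as a block (adjusted p = 0.115 and 0.0847).

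Microglial genes were raised in the arrays labelled SHRSP at 3 weeks, with 9 of 17 raised and 0 lowered, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.995 with an estimated correlation). C1qc, a complement subunit, rose by 0.73 ± 0.14, Tmem119 by 0.71 ± 0.14, Trem2 by 0.54 ± 0.08 and Laptm5 by 0.38 ± 0.07. Immediate early genes, which neurons induce on activity, were lowered, with 0 of 25 raised and 10 lowered, and the same numbers adjusted over the list alone (adjusted p = 0.0251; adjusted p = 0.995 with an estimated correlation). Nr4a1 fell by 1.02 ± 0.09, Fos by 0.81 ± 0.10, Fosb by 0.76 ± 0.12 and Nr4a2 by 0.30 ± 0.05. Of 60 cytosolic ribosomal protein genes 14 rose and 3 fell, with 6 and 3 adjusted over the list alone (adjusted p = 0.0221; adjusted p = 0.995 with an estimated correlation). None of these 3 shifts was called with slide as a block (adjusted p = 0.255, 0.555 and 0.555), after quantile normalization (adjusted p = 0.0786, 0.0608 and 0.775) or after normexp (adjusted p = 0.085, 0.085 and 0.163), though the microglial median of 0.26 stayed at 0.27 and 0.25. With the block the ribosomal list pointed down, and of the 8 named genes only Nr4a1 was called (log2 -0.67). No slide held both groups, and in the block SHR replicate 1 alone links them.

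Of 21 measured candidate hypertension genes, 4 rose and 8 fell in the arrays labelled SHRSP at 3 weeks and 5 and 8 adjusted over the list alone (list adjusted p = 0.783). Cyp11b1 rose by log2 0.48 ± 0.07, Agt by 0.30 ± 0.06 and Gstm1 by 0.26 ± 0.04. The calcium sensor gene Stim1 fell by 0.50 ± 0.06, Chga by 0.60 ± 0.11 and the angiotensin receptor gene Agtr1a by 0.25 ± 0.08. None of these 6 genes was called with slide as a block (adjusted p between 0.0632 and 0.941). In total 8594 genes were called, 3653 raised and 4941 lowered (42.5% raised, 57.2% after quantile normalization). The count was 1047 with slide as a fixed block and 5170 with a random slide block. Of the 31 largest named changes, 31 had the same direction with slide as a block and 26 were called.

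The comparison of SHRSP with SHR at 3 weeks asks what sets these strains apart. Fewer genes differed than from WKY, and most of the largest differences followed the opposite label at 6 weeks. In the arrays labelled SHRSP, Agtrap was lower by log2 4.06 ± 0.05 (SE, n = 3; adjusted p = 2.31e-15), Ephx2 was lower by 3.92 ± 0.19 and Nppa by 1.17 ± 0.08. Vegfb was under background in the arrays labelled SHR and at least 292-fold higher in those labelled SHRSP, Defb17 was at least 43.8-fold higher, and Hba-a3 was at least 121-fold lower. Zfp597 rose by 2.78 ± 0.07, Zfp296 by 2.29 ± 0.08, Serhl2 by 2.06 ± 0.07 and Zap70, a T cell receptor kinase, by 1.67 ± 0.06. Haghl fell by 1.83 ± 0.07, Tnfaip6, a hyaluronan-binding protein of inflamed tissue, by 1.80 ± 0.07, Myoc, myocilin, by 1.56 ± 0.09 and Lpar6, a lysophosphatidic acid receptor, by 1.37 ± 0.06. The leukocyte receptor genes Lilrb3l and Pira2 were at least 12.7-fold and at least 3.61-fold lower. Within the slide block, which here rests on slide 2, the values were -4.07 for Agtrap, -3.80 for Ephx2, 2.72 for Zfp597, 2.03 for Serhl2, -1.94 for Haghl and -1.71 for Tnfaip6, all called. For Lilrb3l a second probe did not give the same call.

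Oligodendrocyte and myelin genes were lower in the arrays labelled SHRSP at 3 weeks, with 3 of 22 lowered and 0 raised over all genes, and 13 lowered and 1 raised adjusted over the list alone (adjusted p = 1.81e-07; adjusted p = 0.134 with an estimated correlation). Opalin fell by 0.40 ± 0.05, Ermn by 0.25 ± 0.05 and Ppp1r14a by 0.23 ± 0.04. Of 26 interferon response genes 3 fell, with 8 adjusted over the list alone (adjusted p = 3.89e-07). Cxcl10, a chemokine, fell by 1.52 ± 0.29 and the guanylate-binding protein genes Gbp5 and Gbp2 by 0.54 ± 0.10 and 0.53 ± 0.14. Of 24 cholesterol synthesis genes 5 fell, with 10 adjusted over the list alone (adjusted p = 3.89e-07), among them Hsd17b7 by 0.58 ± 0.05. Both of these lists had adjusted p = 0.387 with an estimated correlation. The 3 lists were also lowered with slide as a block (adjusted p between 2.28e-07 and 4.15e-05), with means within slide 2 of -0.14, -0.34 and -0.17. Ermn, Cxcl10 and Gbp2 were then not called (adjusted p between 0.0608 and 0.137). Circadian genes were raised, with 5 of 19 raised and 2 lowered, and 7 and 2 adjusted over the list alone (adjusted p = 0.00779; adjusted p = 0.134 with an estimated correlation). Per2 rose by 0.73 ± 0.09 and Bhlhe40 by 0.37 ± 0.06, while Bmal1 fell by 0.29 ± 0.04 and Nfil3 by 0.48 ± 0.07. Of 21 candidate hypertension genes 5 fell, over all genes and adjusted over the list alone (adjusted p = 0.000987; adjusted p = 0.155 with an estimated correlation). Ephx2 and Nppa were among them, as were Cd36, which fell by 0.47 ± 0.12, and Stim1, which fell by 0.33 ± 0.06. Neither of these 2 lists was called with slide as a block (adjusted p = 0.0548 and 0.0615; means within slide 2 of 0.10 and -0.33), nor were Bhlhe40 and Cd36 (adjusted p = 0.0649 and 0.0529).

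Meningeal and antigen presentation genes were lowered and unfolded protein and microglial genes raised as lists between the arrays labelled SHRSP and SHR at 3 weeks, with 1, 0, 0 and 1 members called. Adjusted over the list alone, 0 rose and 5 fell, 0 changed, 0 changed and 1 rose. Their adjusted p were 0.000628, 0.00783, 0.0227 and 0.0276, with medians of -0.14, -0.10, 0.09 and 0.11, and with an estimated correlation they had adjusted p = 0.507, 0.543, 0.398 and 0.672. Aldh1a2, a retinoic acid synthetic enzyme, fell by 0.43 ± 0.11 and P2ry12 rose by 0.45 ± 0.09, and neither was called with slide as a block (adjusted p = 0.258 and 0.203). Of the 4 lists only antigen presentation was called with the block (adjusted p = 0.0274, the others between 0.0792 and 0.317), and the means within slide 2 were -0.08, -0.10, 0.04 and 0.04. The unfolded protein and microglial calls were lost without SHR replicate 1 (adjusted p = 0.0562 and 0.118) or SHRSP replicate 3 (adjusted p = 0.0639 and 0.115), the unfolded protein call without SHR replicate 2 (adjusted p = 0.0856) and the antigen presentation call without SHR replicate 3 (adjusted p = 0.0796). With fry the meningeal, antigen presentation and microglial lists had adjusted p = 0.0646, 0.134 and 0.321, and the microglial list had adjusted p = 0.0529 after quantile normalization.

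In total 898 genes were called between the arrays labelled SHRSP and SHR at 3 weeks, 475 raised and 423 lowered, and 75 of them were at least 2-fold apart. The count was 495 with slide as a fixed block and 855 with a random slide block. Of the 38 largest named changes, 38 had the same direction with slide as a block and within slide 2, and 27 were called with the block. A fit of these groups alone called 287.

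The comparison of SHR with WKY at 6 weeks asks how the brains differ when blood pressure begins to rise. In the arrays labelled SHR, Agtrap was lower by 4.51 ± 0.05 (SE, n = 3; adjusted p = 5.42e-16), Ephx2 by 3.75 ± 0.19 and Nppa by 1.27 ± 0.08, which at 3 weeks were low in the arrays labelled SHRSP. Zfp597 rose by 2.59 ± 0.07 and Zfp296 by 2.35 ± 0.08. Cort, the cortistatin gene of cortical interneurons, fell by 1.91 ± 0.05 and the receptor phosphatase gene Ptprj by 1.93 ± 0.05, for which a second probe did not give the same call. Oxnad1 was at least 16.0-fold higher and the odorant receptor gene Or5aq6 at least 3.39-fold lower. Or8b8 and Agtr1b rose by 2.69 ± 0.44 and 2.59 ± 0.43, the reverse of 3 weeks, where neither was called with slide as a block.

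Myelin genes were lowered in the arrays labelled SHR at 6 weeks, with 16 of 22 lowered and 2 raised over all genes and adjusted over the list alone (adjusted p = 4.07e-06; adjusted p = 0.463 with an estimated correlation). Cnp fell by 0.71 ± 0.07 and Enpp6 by 0.70 ± 0.05. Microglial genes were raised, with 12 of 17 raised and 0 lowered, again in both counts (median 0.48; adjusted p = 0.000354; adjusted p = 0.594 with an estimated correlation). Tmem119 rose by 0.95 ± 0.14 and C1qa by 0.84 ± 0.12. Of 24 cholesterol synthesis genes 13 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.000354; adjusted p = 0.561 with an estimated correlation), with Hsd17b7 lower by 0.49 ± 0.05. Of 28 antigen presentation genes 16 rose and 3 fell in both counts (adjusted p = 0.0217; adjusted p = 0.655 with an estimated correlation), with RT1-CE4 higher by 0.74 ± 0.08 and RT1-A2 by 0.64 ± 0.09. Of 60 ribosomal protein genes 17 fell and 4 rose, with 16 and 4 adjusted over the list alone (adjusted p = 0.00173; adjusted p = 0.796 with an estimated correlation), and this call was lost after quantile normalization (adjusted p = 0.562) and with fry in place of camera (adjusted p = 0.145). After normexp the antigen presentation list had an adjusted p of 0.092.

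Hypoxia genes rose in the arrays labelled SHR at 6 weeks, with 9 of 19 raised and 0 lowered, and 10 and 0 adjusted over the list alone. Adm, adrenomedullin, rose by log2 0.60 ± 0.07 and P4ha1 by 0.39 ± 0.06. Of 22 genes of the unfolded protein response and heat shock 10 rose and 3 fell, with 14 and 3 adjusted over the list alone. The heat shock gene Hspa1b rose by 1.95 ± 0.14, Herpud1 by 0.42 ± 0.05 and Xbp1 by 0.40 ± 0.04, while Atf3 fell by 1.11 ± 0.14. Of 25 GABA genes 6 fell and 1 rose, with 5 and 1 adjusted over the list alone, and Sst fell by 0.74 ± 0.07 and the GABA-synthetic enzyme gene Gad2 by 0.50 ± 0.06. Of 23 genes of immature neurons and brain growth 9 fell and 2 rose in both counts, and Sox4 fell by 0.48 ± 0.07 and Cd24 by 0.36 ± 0.06. Each of these 4 lists had a camera adjusted p of 0.0297, and an adjusted p of 0.561 with an estimated correlation. All 4 calls were lost after normexp (adjusted p = 0.125, 0.242, 0.0619 and 0.0999), those of GABA and immature neurons after quantile normalization (adjusted p = 0.0932 each) and those of hypoxia and unfolded protein without SHR replicate 3 (adjusted p = 0.0909 and 0.0687).

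Of 21 candidate hypertension genes, Agtr1b and 8 others rose and 4 fell in the arrays labelled SHR at 6 weeks (list adjusted p = 0.663), 8 of these 13 also with a random slide block. Cd36 rose by log2 0.61 ± 0.12, Spon1 by 0.46 ± 0.06 and the adrenaline-synthetic enzyme gene Pnmt by 0.38 ± 0.07. Ephx2 and Nppa were among those that fell, and the angiotensin converting enzyme gene Ace fell by 0.34 ± 0.08. In total 8669 genes were called, 5403 raised and 3266 lowered (62.3% raised, 42.1% after quantile normalization). A random slide block called 5392, among them all of the 32 largest named changes. The arrays labelled SHR filled slide 4 and WKY shared slide 3 with 1 SHRSP array of 3 weeks, so slide and strain cannot be told apart here.

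The comparison of SHRSP with WKY at 6 weeks asks the same. Immediate early genes, the list with the lowest median of all comparisons, fell in the arrays labelled SHRSP at 6 weeks. Of 25 measured, 19 fell and 0 rose, with 19 and 1 adjusted over the list alone (median log2 -0.73; adjusted p = 2.03e-15; adjusted p = 0.00465 with an estimated correlation). The transcription factor genes Fos, Nr4a1 and Egr2 fell by 2.54 ± 0.10, 2.18 ± 0.09 and 2.07 ± 0.16 (SE, n = 3), the synaptic gene Arc by 2.11 ± 0.13 and the kinase gene Sik1 by 0.76 ± 0.06. Vegfb was under background in all 3 arrays and at least 209-fold lower, and Lilrb3l and Pira2 were at least 11.1-fold and at least 3.07-fold higher. Ltbp2, a matrix protein, rose by 2.25 ± 0.11, while Serhl2 fell by 1.87 ± 0.07.

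Meningeal and fibroblast genes were raised in the arrays labelled SHRSP at 6 weeks, with 17 of 19 raised and 0 lowered, and 19 adjusted over the list alone (adjusted p = 3.93e-07; adjusted p = 0.369 with an estimated correlation). Lum, lumican, rose by 0.98 ± 0.15, Igf2 by 0.49 ± 0.05 and Ptgds by 0.43 ± 0.05. On the same arrays the choroid plexus median lay between -1.60 and -1.26, against -2.74 to -1.91 in WKY, and the pineal median between -4.40 and -2.46, against -4.99 to -4.80, and adjoining tissue in the dissection was not tested here. Microglial genes were raised, with 14 of 17 raised and 0 lowered (median 0.47; adjusted p = 6.43e-06; adjusted p = 0.486 with an estimated correlation), as were antigen presentation genes, with 19 of 28 raised and 0 lowered (adjusted p = 6.43e-06; adjusted p = 0.412 with an estimated correlation). Both counts were the same adjusted over the list alone. The complement gene C1qb rose by 0.75 ± 0.09, the class II gene RT1-Da by 0.74 ± 0.10 and Trem2 by 0.68 ± 0.08. Of 12 genes of oligodendrocyte precursors 4 fell and 0 rose, with 5 and 0 adjusted over the list alone (adjusted p = 0.00639; adjusted p = 0.369 with an estimated correlation), with Sox4 lower by 0.73 ± 0.07 and Ptprz1 by 0.62 ± 0.07. Of 25 GABA genes 8 fell and 3 rose in both counts (adjusted p = 0.0245; adjusted p = 0.412 with an estimated correlation), with Sst lower by 0.69 ± 0.07 and Gad2 by 0.45 ± 0.06. Of 17 genes of ependymal cilia 10 rose and 0 fell, with 11 and 0 adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.412 with an estimated correlation). Of 41 genes of oxidative phosphorylation 12 rose and 1 fell in both counts (adjusted p = 0.0338; adjusted p = 0.809 with an estimated correlation), and this call was lost after quantile normalization (adjusted p = 0.521). Without WKY replicate 2 the cilia and oxidative phosphorylation lists had adjusted p = 0.0576 and 0.0714, and the latter had adjusted p = 0.106 without SHRSP replicate 3.

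Of 21 candidate hypertension genes, 6 rose and 1 fell in the arrays labelled SHRSP at 6 weeks (list adjusted p = 0.11), 3 of these 7 also with a random slide block, beside 31.6% called of all genes. Cd36 rose by log2 0.69 ± 0.12 and Spon1 by 0.36 ± 0.06. The photoreceptor and pineal genes Aipl1, Gnb3, Guca1a and Gngt2 rose by 3.30 ± 1.12, 2.33 ± 0.81, 2.31 ± 0.65 and 2.28 ± 0.52, unequally between the 3 arrays. None of these 4 was called with the block (adjusted p between 0.0645 and 0.23). In total 6693 genes were called, 4292 raised and 2401 lowered (64.1% raised, 48.4% after quantile normalization), and 3210 with a random slide block. Of the 36 largest named changes 30 were called with that block. Slide 5 held only the arrays labelled SHRSP at 6 weeks, so slide and strain cannot be told apart here.

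The comparison of SHRSP with SHR at 6 weeks asks what sets them apart at the older age. In the arrays labelled SHRSP, Agtrap was higher by log2 4.56 ± 0.05 (SE, n = 3; adjusted p = 4.69e-16), Ephx2 by 3.65 ± 0.19 and Nppa by 1.47 ± 0.08, each the reverse of the labels at 3 weeks. Myoc rose by 2.04 ± 0.09 and Haghl by 2.03 ± 0.07. Zfp597 fell by 2.81 ± 0.07 and Hspa1b by 2.31 ± 0.14. Vegfb was at least 195-fold lower and Defb17 at least 41.9-fold lower, while Pira2 was at least 2.66-fold higher.

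Immediate early genes were lower in the arrays labelled SHRSP than in those labelled SHR at 6 weeks, with 22 of 25 lowered and 0 raised, and 22 and 1 adjusted over the list alone (median log2 -0.63; adjusted p = 3.53e-11; adjusted p = 0.018 with an estimated correlation). Egr2 fell by 2.42 ± 0.16, Arc by 2.22 ± 0.13 and Fos by 2.17 ± 0.10. Ribosomal protein genes were raised, with 29 of 60 raised and 0 lowered and 32 adjusted over the list alone (adjusted p = 5.64e-06; adjusted p = 0.79 with an estimated correlation), and so were genes of oxidative phosphorylation, with 17 of 41 raised and 2 lowered in both counts (adjusted p = 0.00324; adjusted p = 0.721 with an estimated correlation). Both calls were lost after quantile normalization (adjusted p = 0.608 and 0.966). Of 22 myelin genes 15 rose and 1 fell in both counts (adjusted p = 2.6e-05; adjusted p = 0.41 with an estimated correlation), with Nkx6-2 higher by 0.67 ± 0.07 and Ppp1r14a by 0.41 ± 0.04. Of 19 meningeal genes 11 rose and 0 fell, with 13 adjusted over the list alone (adjusted p = 0.000387; adjusted p = 0.721 with an estimated correlation). Of 32 genes of glutathione and oxidative stress 14 rose and 2 fell, with 16 and 2 adjusted over the list alone (adjusted p = 0.0389; adjusted p = 0.721 with an estimated correlation), with Gstm2 higher by 0.50 ± 0.08 and Gstm3 at least 1.45-fold lower. Of 16 choroid plexus genes 5 rose and 1 fell in both counts (adjusted p = 0.0417; adjusted p = 0.79 with an estimated correlation), with the clotting factor gene F5 higher by 0.99 ± 0.30 and the water channel gene Aqp1 by 0.63 ± 0.21, neither called with a random slide block (adjusted p = 0.111 and 0.133). The glutathione and choroid calls were lost after quantile normalization (adjusted p = 0.111 and 0.0761; median log2 0.119 and 0.634, against 0.132 and 0.525) and without SHRSP replicate 1 (adjusted p = 0.0665 and 0.116), and the choroid call also without SHR replicate 1 (adjusted p = 0.435) and with fry (adjusted p = 0.102).

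In total 9091 genes were called between the arrays labelled SHRSP and SHR at 6 weeks, 4612 raised and 4479 lowered (39 and 565 at least 2-fold), and 4756 with a random slide block. Of the candidate hypertension genes, Ace rose by log2 0.69 ± 0.08. Of the 38 largest named changes 33 were called with the random block. The 2 groups were on slides 5 and 4, which held no other arrays, so slide and strain cannot be told apart here.

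Across the 2 ages, 46 genes were raised and 53 lowered in the arrays labelled SHRSP against SHR at both, against 103 and 89 for independent calls, and 486 were called in opposite directions (r across genes 0.04). Among the largest with 1 direction, Foxq1, a forkhead factor, was higher by log2 0.61 ± 0.12 (SE, n = 3) and 0.65 ± 0.12 at 3 and 6 weeks, Itga9 by 0.46 ± 0.09 and 0.54 ± 0.09, Mfsd2a, a lipid transporter of the blood-brain barrier, by 0.48 ± 0.05 and 0.27 ± 0.05, and the clock-controlled gene Dbp by 0.40 ± 0.10 and 0.48 ± 0.10. Apold1, an early response gene of endothelium, fell by 1.04 ± 0.13 and 1.18 ± 0.13 and Depp1 by 0.89 ± 0.22 and 1.44 ± 0.22. Dusp1 fell by 0.62 ± 0.16 and 0.64 ± 0.16, Nr4a1 by 0.50 ± 0.09 and 1.51 ± 0.09 and Nfil3 by 0.48 ± 0.07 and 0.71 ± 0.07. Mfsd2a, Itga9, Nfil3, Dusp1 and Apold1 were called with slide as a block at 3 weeks (adjusted p between 0.0126 and 0.0491), and Foxq1, Dbp, Depp1 and Nr4a1 were not.

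The comparison of 6 with 3 weeks in WKY asks what changes in the normotensive brain with age. Genes of neuronal maturation rose. Of 21 genes of perineuronal nets, potassium channels and late maturation 13 rose and 0 fell in both counts, over all genes and adjusted over the list alone (adjusted p = 0.000534; adjusted p = 0.383 with an estimated correlation), with the kinase gene Camk2a higher by log2 0.33 ± 0.06 (SE, n = 3), Syt2 by 0.32 ± 0.06 and the channel gene Kcna1 by 0.29 ± 0.05. Of 25 immediate early genes 18 rose and 2 fell, with 20 and 3 adjusted over the list alone (adjusted p = 8.07e-05; adjusted p = 0.204 with an estimated correlation), with Egr2 higher by 1.03 ± 0.16 and Fos by 0.77 ± 0.10. Of 19 circadian genes 12 rose and 2 fell, with 13 and 2 adjusted over the list alone (adjusted p = 0.00135; adjusted p = 0.0694 with an estimated correlation), with Bhlhe41 higher by 0.72 ± 0.10, Clock by 0.63 ± 0.09 and Nr1d1 by 0.51 ± 0.07. Microglial genes fell, 14 of 17 with 0 raised in both counts (adjusted p = 8.07e-05; adjusted p = 0.514 with an estimated correlation), with Fcrl2 lower by 1.11 ± 0.14, the growth factor receptor gene Csf1r by 0.67 ± 0.11 and Ctss by 0.60 ± 0.10. Of 26 cell cycle genes 14 fell and 0 rose in both counts (adjusted p = 0.00129; adjusted p = 0.446 with an estimated correlation), with Top2a lower by 0.82 ± 0.16 and Cdk1 by 0.48 ± 0.08. Of 24 cholesterol synthesis genes 14 fell and 0 rose, with 17 adjusted over the list alone (adjusted p = 0.00014; adjusted p = 0.508 with an estimated correlation), with Fdft1 lower by 0.65 ± 0.09, Fdps by 0.63 ± 0.07 and Sqle by 0.47 ± 0.04. Of 41 genes of oxidative phosphorylation 24 fell and 0 rose, with 24 and 1 adjusted over the list alone (adjusted p = 0.00014; adjusted p = 0.463 with an estimated correlation), with Cox5a lower by 0.42 ± 0.05. These 7 shifts were also called with slide as a block (adjusted p between 4.15e-08 and 0.0367), but of the named genes only Egr2 (log2 1.76), Fos (1.08), Fdps (-0.78) and Sqle (-0.55) were.

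GABA, glutamate, astrocyte and ribosomal lists rose in WKY but were not called with slide as a block. Of 25 GABA genes 14 rose and 3 fell, with 14 and 4 adjusted over the list alone (adjusted p = 0.017), with Gabrb1 higher by log2 0.41 ± 0.07 and Gad2 by 0.40 ± 0.06. Of 25 glutamate genes 11 rose and 2 fell, with 12 and 2 adjusted over the list alone (adjusted p = 0.0454), with the receptor subunit genes Grik3 and Grin2a higher by 0.52 ± 0.08 and 0.38 ± 0.06. Of 17 astrocyte genes 8 rose and 0 fell in both counts (adjusted p = 0.0354), with Gfap, the glial filament gene, higher by 0.30 ± 0.05. Of 60 ribosomal protein genes 34 rose and 2 fell, with 37 and 2 adjusted over the list alone (adjusted p = 3.2e-05). These 4 lists had adjusted p = 0.446, 0.463, 0.514 and 0.583 with an estimated correlation, and 0.145, 0.276, 0.195 and 0.837 with slide as a block, with which only Grik3 of the named genes was called (log2 0.46). The GABA, glutamate and astrocyte calls were lost after normexp (adjusted p = 0.118, 0.131 and 0.131), and the latter 2 after quantile normalization (adjusted p = 0.0682 and 0.091) and without WKY 3-week replicate 1 (adjusted p = 0.0601 and 0.051).

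The largest single changes with age in WKY mostly did not hold with slide as a block. Rbsn rose by log2 1.40 ± 0.17 and Or5aq6 by at least 3.59-fold, and these 2 and Egr2 were called with the block (adjusted p between 0.0296 and 0.0409). Bicc1 and the activity-dependent gene Npas4 rose by 1.06 ± 0.15 and 1.25 ± 0.42, while Or8b8, Agtr1b and Snx15 fell by 2.50 ± 0.44, 2.40 ± 0.43 and 1.79 ± 0.35. None of these 5 was called with the block, and Npas4 then had the opposite sign. In total 9360 genes were called, 4783 raised and 4577 lowered (25 and 482 at least 2-fold), 5445 with a random and 803 with a fixed slide block, and 3452 with a block on scan day. Of the 22 largest named changes 19 kept direction with slide as a block and 4 were called. The WKY groups shared no slide and were linked through 3-week SHR replicate 1 and SHRSP replicate 3.

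The comparison of 6 with 3 weeks in SHR asks what changes in the hypertensive brain over the same time, taking the labels as given. Myelin genes were lower in the arrays labelled SHR at 6 weeks, with 19 of 22 lowered and 0 raised in both counts, over all genes and adjusted over the list alone (adjusted p = 3.62e-15; adjusted p = 0.0237 with an estimated correlation). The myelin protein genes Cnp and Cldn11 fell by log2 0.98 ± 0.07 and 0.87 ± 0.06 (SE, n = 3). Of 26 cell cycle genes 18 fell and 1 rose, with 19 and 1 adjusted over the list alone (adjusted p = 1.17e-08; adjusted p = 0.0426 with an estimated correlation), with the mitotic kinase gene Cdk1 lower by 1.06 ± 0.08. Of 19 circadian genes 13 rose and 1 fell, with 14 and 1 adjusted over the list alone (adjusted p = 0.00418; adjusted p = 0.0426 with an estimated correlation), with Per2 higher by 0.79 ± 0.09 and Bhlhe40 by 0.75 ± 0.06. Of 24 cholesterol synthesis genes 21 fell and 1 rose in both counts (adjusted p = 1.72e-14; adjusted p = 0.0716 with an estimated correlation), with Tm7sf2 lower by 0.99 ± 0.06. Of 41 genes of oxidative phosphorylation 23 fell and 0 rose, with 23 and 1 adjusted over the list alone (adjusted p = 1.04e-07; adjusted p = 0.151 with an estimated correlation). Of 23 genes of immature neurons 10 fell and 3 rose in both counts (adjusted p = 0.00399; adjusted p = 0.188 with an estimated correlation). The median of 13 Hox genes of the hindbrain and spinal cord, chosen after their values were seen, lay between -5.22 and -4.86 on the SHR arrays of 3 weeks and between -6.25 and -5.62 on those of 6 weeks. Over all 3 strains it lay between -5.38 and -4.86 and between -6.29 and -5.02, and a difference in dissection between the ages was not tested in any strain.

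Immediate early and unfolded protein genes rose from 3 to 6 weeks in the arrays labelled SHR. Of 25 immediate early genes 18 rose and 0 fell in both counts (adjusted p = 5.19e-05; adjusted p = 0.0837 with an estimated correlation), with Ptgs2, the inducible cyclooxygenase gene, higher by log2 0.98 ± 0.08 and Nr4a3 by 0.93 ± 0.10. Of 22 genes of the unfolded protein response and heat shock 13 rose and 0 fell, with 13 and 1 adjusted over the list alone (adjusted p = 0.00345; adjusted p = 0.151 with an estimated correlation), with Hspa1b higher by 2.43 ± 0.14. Of 28 antigen presentation genes 15 rose and 0 fell, with 16 adjusted over the list alone, and of 21 genes of late maturation 13 rose and 1 fell, with 14 and 1 adjusted over the list alone. These 2 lists each had an adjusted p of 0.0485 (adjusted p = 0.636 and 0.478 with an estimated correlation), with RT1-A2 higher by 0.67 ± 0.09 and Kcna2 by 0.51 ± 0.06. Both calls were lost after normexp (adjusted p = 0.109 and 0.198) and without SHR 3-week replicate 1 (adjusted p = 0.15 and 0.121), and the antigen presentation call after quantile normalization (adjusted p = 0.0676).

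Several genes with a large change in the arrays labelled SHR from 3 to 6 weeks were among those that followed opposite labels. Zfp597 rose by log2 2.95 ± 0.07, Zfp296 by 2.53 ± 0.08 and Serhl2 by 1.97 ± 0.07, while Agtrap fell by 4.45 ± 0.05, Ephx2 by 3.84 ± 0.19, Cort by 2.43 ± 0.05 and Nppa by 1.33 ± 0.08. Vegfb was at least 260-fold higher, Defb17 at least 55.9-fold higher, and Lilrb3l was at least 11.2-fold lower. The lipoxygenase gene Alox15 fell by 2.03 ± 0.17. Hoxb8, a gene of the hindbrain and spinal cord, was at least 7.56-fold lower. Of the candidate hypertension genes Ogn rose by 0.48 ± 0.08 and Gstm1 by 0.16 ± 0.04, while Cd36 fell by 0.48 ± 0.12 and Agtr1a by 0.32 ± 0.08. In total 10223 genes were called, 7003 raised and 3220 lowered (68.5% raised, 43.3% after quantile normalization, which moved the median over all genes from 0.09 to -0.02), 6674 with a random slide block and 1718 with a block on scan day. Of the 22 largest named changes 19 were called with the random block, and the SHR arrays of the 2 ages shared no slide.

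The comparison of 6 with 3 weeks in SHRSP asks the same, taking the labels as given. Antigen presentation genes were higher in the arrays labelled SHRSP at 6 weeks, with 22 of 28 raised and 0 lowered and 23 adjusted over the list alone (adjusted p = 1.35e-08; adjusted p = 0.174 with an estimated correlation), with Cd74 higher by log2 0.99 ± 0.13 (SE, n = 3) and RT1-Da by 0.86 ± 0.10. Of 19 meningeal genes 16 rose and 0 fell, with 17 adjusted over the list alone (adjusted p = 9.38e-08; adjusted p = 0.174 with an estimated correlation), with Igf2 higher by 0.75 ± 0.05 and Crabp2 by 0.73 ± 0.08. Of 26 interferon genes 11 rose and 0 fell, with 16 adjusted over the list alone (adjusted p = 0.000105; adjusted p = 0.433 with an estimated correlation), with Cxcl10, above background on 2 of 3 arrays at 3 weeks, higher by 2.05 ± 0.29 and Ifitm1 by 0.67 ± 0.07. Of 23 genes of inflammation and the acute phase 12 rose and 1 fell, with 12 and 2 adjusted over the list alone (adjusted p = 0.0174; adjusted p = 0.334 with an estimated correlation), with the complement gene C4a higher by 0.79 ± 0.09. Of 60 ribosomal protein genes 31 rose and 0 fell, with 34 adjusted over the list alone (adjusted p = 0.000124; adjusted p = 0.636 with an estimated correlation).

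Lowered lists in the arrays labelled SHRSP from 3 to 6 weeks were those of cholesterol synthesis, oxidative phosphorylation, cell cycle, immediate early genes, myelin, microglia and oligodendrocyte precursors. Their camera adjusted p were 1.36e-08, 2.08e-05, 2.25e-05, 0.000122, 0.000468, 0.000468 and 0.00109, and with an estimated correlation adjusted p = 0.186, 0.255, 0.174, 0.174, 0.255, 0.573 and 0.174. Of 24 cholesterol genes 11 fell and 2 rose, with 13 and 2 adjusted over the list alone. Of 41 genes of oxidative phosphorylation 7 fell and 0 rose, with 5 adjusted over the list alone. Of 26 cell cycle genes 8 fell and 1 rose in both counts, and Cdk1 fell by log2 0.64 ± 0.08. Of 25 immediate early genes 7 fell and 3 rose, with 9 and 4 adjusted over the list alone, and Fos fell by 0.96 ± 0.10 and Arc by 0.87 ± 0.13. Of 22 myelin genes 10 fell and 4 rose in both counts, with Tf, transferrin, higher by 0.48 ± 0.04. Of 17 microglial genes 4 fell and 1 rose in both counts, with Fcrl2 lower by 1.24 ± 0.14 and P2ry12 by 0.50 ± 0.09. Of 12 precursor genes 3 fell and 0 rose in both counts, and Neu4 fell by 0.52 ± 0.07. With fry in place of camera the myelin and microglial lists had adjusted p = 0.0817 and 0.129.

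Among genes that followed opposite labels, Agtrap rose with age in the arrays labelled SHRSP by log2 4.17 ± 0.05, Ephx2 by 3.74 ± 0.19 and Nppa by 1.31 ± 0.08. Of these Zfp597 fell by 2.64 ± 0.07, Rgs11 by 2.01 ± 0.15 and Zfp296 by 1.88 ± 0.08. Of these Hba-a3 was at least 96.0-fold higher, and Vegfb and Defb17 at least 219-fold and 32.8-fold lower. The pituitary genes Gh1, Tshb and Cga rose at least 92.9-fold, at least 29.8-fold and by 3.64 ± 1.11. Replicate 2 of 6 weeks held most of the signal (Gh1 at 5.82, the others at -6.45 and -2.96). These 3 genes were not called with a random slide block (adjusted p = 0.195, 0.119 and 0.136). Of the candidate hypertension genes Ace rose by 0.70 ± 0.08 and Stim1 by 0.46 ± 0.06. In total 5294 genes were called, 4096 raised and 1198 lowered (77.4% raised, 45.2% after quantile normalization). A random slide block called 2180, 17 of the 22 largest named changes among them, and without SHRSP 3-week replicate 2 the count was 3496. The ages shared no slide.

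The interaction of strain and age asks whether the change from 3 to 6 weeks differs between a hypertensive strain and WKY. For SHR, 8320 genes were called, 5142 raised and 3178 lowered (61.8% raised, 38.1% after quantile normalization, which moved the median over all genes from 0.03 to -0.10), and 5251 with a random slide block. Oligodendrocyte and myelin genes fell relative to WKY, with 16 of 22 lowered and 0 raised in both counts, over all genes and adjusted over the list alone (median log2 -0.43; adjusted p = 4.84e-08; adjusted p = 0.215 with an estimated correlation). Of 24 cholesterol synthesis genes 11 fell and 1 rose in both counts (adjusted p = 0.001; adjusted p = 0.809 with an estimated correlation). Of 60 ribosomal protein genes 20 fell and 2 rose in both counts (adjusted p = 0.000499; adjusted p = 0.917 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.628) and with fry in place of camera (adjusted p = 0.103). Of 22 genes of the unfolded protein response and heat shock 13 rose and 0 fell, with 14 and 1 adjusted over the list alone (adjusted p = 0.00702; adjusted p = 0.588 with an estimated correlation), a call lost after normexp (adjusted p = 0.146) and without SHR 3-week replicate 1 (adjusted p = 0.0711). Among the 12 genes with the smallest adjusted p, Zfp597 rose relative to WKY by 2.50 ± 0.10 (SE, n = 3), Zfp296 by 2.41 ± 0.12, Serhl2 by 1.80 ± 0.09, Gpatch11 by 1.31 ± 0.06 and the vesicle transport gene Trappc6a by 1.02 ± 0.05. Agtrap fell by 4.68 ± 0.08, Ephx2 by 4.02 ± 0.26, Haghl by 1.93 ± 0.10, Cort by 1.5 ± 0.07 and Zfp14 by 0.97 ± 0.05, for which a second probe rose by 1.22 (adjusted p = 7.4e-07). Vegfb was called raised and Hba-a3 lowered, without a size because 0 arrays labelled SHR were above background for Vegfb at 3 weeks and 1 for Hba-a3 at 6 weeks. Of the 12, 11 were among the genes that followed opposite labels. Their adjusted p were at most 5.09e-07, and all 12 were called with a random slide block.

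For SHRSP, 6525 genes were called in the interaction of strain and age, 4579 raised and 1946 lowered (70.2% raised, 44.9% after quantile normalization), and 1417 with a random slide block. Immediate early genes fell relative to WKY, with 14 of 25 lowered and 1 raised, and 16 and 1 adjusted over the list alone (median log2 -0.55; adjusted p = 2.71e-08; adjusted p = 0.0558 with an estimated correlation). Of 28 antigen presentation genes 15 rose and 0 fell, with 16 adjusted over the list alone (adjusted p = 0.00126; adjusted p = 0.672 with an estimated correlation). Of 19 circadian genes 6 fell and 1 rose, with 7 and 1 adjusted over the list alone (adjusted p = 0.0152; adjusted p = 0.0758 with an estimated correlation). Of 19 meningeal genes 8 rose and 0 fell, with 9 adjusted over the list alone (adjusted p = 0.0187; adjusted p = 0.707 with an estimated correlation). Without SHRSP 3-week replicate 3 or WKY 6-week replicate 2 the meningeal list had adjusted p = 0.118 or 0.0548. Of 12 genes of oligodendrocyte precursors 4 fell and 0 rose, with 5 and 1 adjusted over the list alone (adjusted p = 0.0187; adjusted p = 0.558 with an estimated correlation). Of 17 astrocyte genes 4 fell and 0 rose in both counts (adjusted p = 0.045; adjusted p = 0.672 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.0675), after normexp (adjusted p = 0.0831) and without any of 7 arrays (adjusted p between 0.0526 and 0.12). Among the 12 genes with the smallest adjusted p, Agtrap rose relative to WKY by 3.94 ± 0.08 (SE, n = 3), Tnfaip6 by 2.02 ± 0.09, Haghl by 1.93 ± 0.10, Lpar6 by 1.61 ± 0.08 and Zfp14 by 1.11 ± 0.05, for which a second probe fell by 1.15 (adjusted p = 1.44e-06). Zfp597 fell by 3.09 ± 0.10, Serhl2 by 2.05 ± 0.09, Zap70 by 1.68 ± 0.09, Trappc6a by 1.39 ± 0.05 and Myl4, a myosin light chain gene, by 1.15 ± 0.06. Hba-a3 was called raised and Vegfb lowered, without a size because 0 arrays labelled SHRSP were above background for Hba-a3 at 3 weeks and for Vegfb at 6 weeks. Of the 12, 10 were among the genes that followed opposite labels. All 12 were called with a random slide block. For all interactions slide and group cannot be told apart at 6 weeks.

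**Figure D2:**
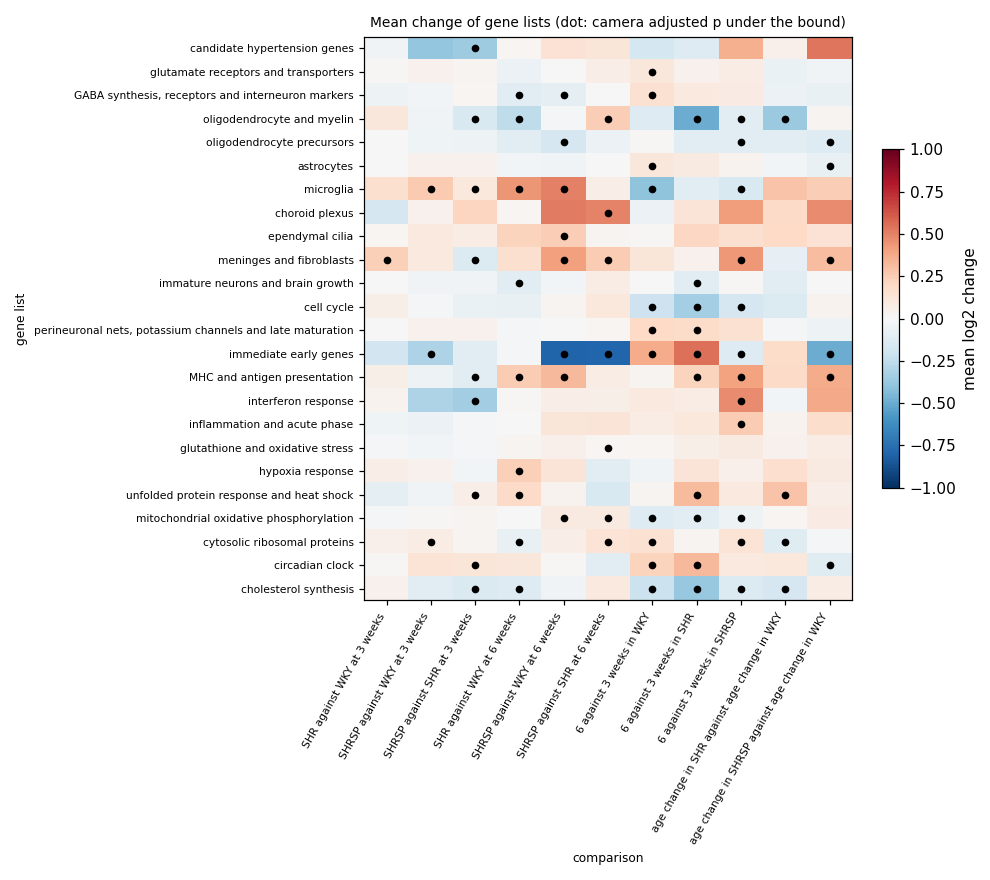
Mean log2 change of the gene lists that passed at least once (vertical axis) in each of the 11 comparisons (horizontal axis), with red for raised, blue for lowered and a dot where the camera adjusted p was under 0.05. Immediate early genes had a mean of -0.80 in the arrays labelled SHRSP against WKY at 6 weeks.

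Of 33 lists 9 passed in none of the 11 comparisons (smallest adjusted p = 0.0647), among them those of catecholamines, dopamine and striatal neurons, endothelium and pericytes, blood cells, pituitary, pineal gland, hypothalamic peptides, and ion transport and arterial pressure. Single genes of the fixed lists did change. Cma1, a chymase that forms angiotensin II, was under background in WKY at 3 weeks, at least 2.49-fold higher in the arrays labelled SHR and called higher in those labelled SHRSP. The glucose transporter gene Slc2a1 of the blood-brain barrier was higher in the arrays labelled SHR and SHRSP by log2 0.53 ± 0.06 and 0.81 ± 0.06 (SE, n = 3) at 3 weeks and the tight junction gene Ocln was lower by 0.84 ± 0.13 and 1.09 ± 0.13. Slc2a1 was called for both with slide as a block, and Cma1 and Ocln for SHR but not for SHRSP (adjusted p = 0.21 and 0.0566). At 6 weeks the vasopressin gene Avp was higher in the arrays labelled SHRSP than in WKY by 0.84 ± 0.13 and the galanin gene Gal by 0.53 ± 0.06.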

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

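The tests of exchanged labels, of slides, of the count after quantile normalization, of the members of the tissue lists and of a second probe of a gene were chosen after the results were seen.

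The interaction of strain and age singled out 8320 genes for the arrays labelled SHR and 6525 for those labelled SHRSP. Among the genes with the smallest adjusted p for SHR, those raised relative to WKY were Vegfb (log2 9.44), Zfp597 (2.5), Zfp296 (2.41), Serhl2 (1.8), Gpatch11 (1.31) and Trappc6a (1.02). Those lowered were Zfp14 (-0.97), Cort (-1.5), Haghl (-1.93), Ephx2 (-4.02), Agtrap (-4.68) and Hba-a3 (-6.26). For SHRSP those raised were Hba-a3 (7.99), Agtrap (3.94), Tnfaip6 (2.02), Haghl (1.93), Lpar6 (1.61) and Zfp14 (1.11). Those lowered were Myl4 (-1.15), Trappc6a (-1.39), Zap70 (-1.68), Serhl2 (-2.05), Zfp597 (-3.09) and Vegfb (-9.41). The values of Vegfb and Hba-a3 rest on groups with 0 or 1 arrays above background and are not measured sizes, and a second probe of Zfp14 was called the other way in both (1.22 and -1.15). Of the 12 genes for each strain 11 and 10 were among the 61 genes below, and an exchange of labels at 1 age would by itself give their interactions.

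Of 100 drawn splits of the strain names within each age, 1, the real one, called as many genes in each interaction. The highest other split called 2 genes for SHR and 58 for SHRSP (real 8320 and 6525). The splits ignored slides, which groups partly followed, so chance and slide stay open. A random slide block called 5251 and 1417. In each of the other 9 comparisons 1 of the 10 splits of the 6 arrays, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The highest other counts at 3 weeks were 6, 0 and 0 (SHR and SHRSP against WKY, SHRSP against SHR). At 6 weeks they were 0, 0 and 2 in that order, and for age 0, 1 and 14 in WKY, SHR and SHRSP.

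Of 75 genes called at least 2-fold apart between the arrays labelled SHRSP and SHR at 3 weeks, 66 were called at 6 weeks, and 61 of these (92.4%, exact interval 83.2% to 97.5%) had the opposite direction, Agtrap, Ephx2, Vegfb and Hba-a3 among them. A difference between slides at 3 weeks is argued against, because 55 of the 61 (90.2%, exact interval 79.8% to 96.3%) were called the same way with slide as a block. Shifts of slides 4 and 5 unrelated to the strain difference are argued against, because at 59 of the 75 genes (78.7%, exact interval 67.7% to 87.3%) both 6-week groups lay nearer the 3-week group of the other label, while a slide difference that follows the labels cannot be told apart from them, since 0 slides held arrays of both groups then. An exchange of the SHR and SHRSP labels at 1 age stays open. Over all genes (r = 0.04) the counts at least 2-fold apart were mixed. The arrays labelled SHRSP at 6 weeks lay nearer SHR (107 genes) than SHRSP (167) of 3 weeks. Those labelled SHR lay further from SHRSP (794) than SHR (610). This cannot decide, as slide 4 lay with slide 1 (first principal component), which held an SHR but no SHRSP array. The data do not say at which age the labels would be exchanged, and a strain difference in maturation stays open, untested.

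SHR replicate 1 of 3 weeks, on slide 1, was over 2-fold apart from replicates 2 and 3, on slide 2, at 522 genes. Scaling between arrays is argued against as the whole cause, because 486 of these genes (93.1%, exact interval 90.6% to 95.1%) stayed 2-fold apart the same way after quantile normalization. Choroid plexus, meninges, pineal gland and blood in amounts that move their genes 2-fold are argued against. Of 59 listed genes 0 were over 2-fold apart (0%, exact interval to 6.1%). Smaller amounts stay open. Pituitary cannot be told apart with 2 of 9 (22.2%, exact interval 2.8% to 60%). The 0.383% of the 522 genes in the 5 lists decides nothing beside 0.321% of all tested genes. A difference between slides stays open. The r across genes, which are not independent replicates, was -0.52 with SHRSP against SHR at 6 weeks and -0.62 with age in WKY. Both had slide 4 or 1 on 1 side. Without these slides r was 0.07 with SHRSP against WKY at 6 weeks and 0.11 with age in SHRSP. The -0.52 was -0.53 after quantile normalization, which cannot exclude a factor for a whole array. No biological explanation was tested.

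Of the genes at least 2-fold from WKY in all 4 comparisons, 19 had another kept probe, and for 11 of these (57.9%, exact interval 33.5% to 79.7%) it was called the same way in all 4. A strain sequence variant under the probe cannot be told apart from a difference in expression for the other genes, because strain sequences were not analysed here. A strain difference in expression, which the design names, stays open as untested.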

How the results depend on the processing

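The block on scan day, the test of nameable genes alone and, for genes called in all 4 comparisons, every alternative but quantile normalization and the replicate block were chosen after the results were seen. For results that moved, the cause was not tested unless given. A random slide block called 3246, 5170, 5392, 3210 and 4756 genes for SHR and SHRSP against WKY at 3 weeks, the same at 6 weeks, and SHRSP against SHR at 6 weeks. It called 5445, 6674 and 2180 for age in WKY, SHR and SHRSP, and 5251 and 1417 for the interactions of SHR and SHRSP. Slide as a fixed block called 1478, 1047 and 495 at 3 weeks (SHR and SHRSP against WKY, SHRSP against SHR) and 803 for age in WKY. Of 524 calls of named genes it turned the sign of 19, among them Aldh1a2 (0.013) in SHRSP against WKY at 3 weeks and Npas4 (-0.31), Spon1 (0.03) and Chga (0.02) for age in WKY. A block on scan day called 3452 for age in WKY and 1718 in SHR. Requiring 2-fold left fewer by construction, 440, 770 and 75 at 3 weeks, 805, 261 and 604 at 6 weeks, 507, 610 and 167 for age and 1700 and 890 for the interactions. Fits of the compared groups alone called 1735 for SHR against WKY and 287 for SHRSP against SHR at 3 weeks. Nameable genes alone, fewer by construction, gave 3770 and 5483 for SHR and SHRSP against WKY at 3 weeks, 5471 and 5830 for SHR against WKY and SHRSP against SHR at 6 weeks, 6023 and 6525 for age in WKY and SHR, and 4906 and 3818 for the interactions. With 1 array left out the counts ranged from 3140 to 7835, 6900 to 7822 and 629 to 809 at 3 weeks, 6968 to 7859, 4670 to 6388 and 7166 to 8495 at 6 weeks, 7629 to 8398, 8121 to 10413 and 3496 to 4558 for age, and 7074 to 9290 and 5356 to 6615 for the interactions. Genes called in 1 direction in all 4 comparisons then ranged from 824 to 1024 and list shifts from 77 to 89, with the lowest share kept, 19 of 24, without SHR 3-week replicate 1. Of 80 list shifts an estimated correlation gave 5 and fry 155 (71 of the 80), and quantile normalization kept 63 and normexp 65, although 7 of the 17 and 1 of the 15 lost shifts had a median at least as large. Of 1306 calls of named genes a random slide block kept 1083, quantile normalization 1236, normexp 1225, the mean of a gene's probes 1248 and a replicate block 1285; a fixed slide block kept 186 of 524. Of the 1306 the mean of probes turned the sign of 14, normexp of 2 and quantile normalization of 0, and the mean of probes turned Zfp14 in the interactions (0.13 and -0.02). Replicate numbers did not pair the arrays, since deviations of 45 same-number pairs correlated at -0.14 to 0.17, over 0.1 in 3. Signal over background limits genes under it in a whole group to a bound, and 1192 of the 1306 calls were of genes well above it on all 18 arrays.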

Other observations

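The values of single arrays and of the principal components were looked up after the results were seen, and the test of neighbouring genes was planned.

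Pituitary genes were high on single arrays. SHRSP replicate 2 of 6 weeks held Gh1, growth hormone, at a scaled log2 intensity of 5.82, Tshb at 1.99, Cga at 2.95 and Pomc, the precursor of corticotropin, at 2.15. SHR replicate 2 of 3 weeks held Pomc at 2.46, and on the other 16 arrays Pomc lay between -1.47 and -0.35. Transthyretin of the choroid plexus (Ttr) lay between 6.24 and 7.40 on all 18 arrays. Hoxb8 lay between -5.94 and -3.94 on the arrays of 3 weeks and at -4.19 on WKY replicate 1 of 6 weeks, and between -9.32 and -7.60 on the other arrays of 6 weeks.

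A hypothesis was tested that genes different from WKY lie close together on the chromosomes. Of 893 genes with a position called in 1 direction in all 4 comparisons with WKY, 650 (72.8%) had another such gene within 1000000 bases. Random sets of the tested genes of the same size had 548 on average and 614 at most (permutation p = 1e-04, 10000 sets). Of those at least 2-fold apart on average 30 of 118 had such a neighbour, against a random mean of 17 and a highest of 38 (permutation p = 0.01). The share of tested genes called in 1 direction in all 4 ranged from 1.2% on chromosome 15 to 9% on chromosome 13.

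The first principal component held 33.3% of the variance, and on it the arrays of slides 1 and 4 lay between -35.4 and -13.5 and the others between 9.9 and 27.1. The fourth held 8.6%, and on it the arrays labelled SHR at 3 weeks and SHRSP at 6 weeks lay between 3.2 and 21.7 and those labelled SHRSP at 3 weeks and SHR at 6 weeks between -19.1 and -9.1. Probes without a gene name had a median scaled log2 intensity of -2.78 to -2.60 on the arrays of slides 1 and 4 and of -3.12 to -2.96 on the others.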
